A study of Mus musculus with 2 samples.

How the data were processed

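The data are single-nucleus RNA sequencing of the tibialis anterior muscle of 1-month-old C57BL6 mice. There were 2 libraries, 1 from wild-type mice and 1 from mice with a deletion of exon 51 of Dmd, named the deletion library here. Per the labels, nuclei were extracted, stained with Hoechst, sorted by flow cytometry and put through droplet-based 3′ gene expression chemistry. The labels do not say how many animals gave each library.

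The deposited main matrices hold counts: per the file headers, whole numbers of unique molecular identifiers (UMIs) per gene and nucleus, made by the authors with Cell Ranger (the header gives software version 3.1.0) on the mouse builds named mm10 and GRCm38, with Seurat also named among the tools. Whether intronic reads were counted is not given in the sources used here. The deposited second set of matrices, named strained, holds expected counts (estimated counts with decimals) for the same nuclei and genes; these were never above the main counts and added up to 80.0% of them in both libraries. The tool that took the difference away is not given in the sources used here. The main values come from the whole-number counts, since counting intervals hold for them, and the strained values served as an alternative. Gene positions and exons come from GENCODE release M21 by Ensembl ID, which matched 30934 of 31053 IDs.

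The files held 7095 wild-type and 4486 deletion nuclei, with at least 500 UMIs in every nucleus. Nuclei were kept with at least 200 genes and at most 5% mitochondrially encoded UMIs, which left 6107 and 2981. Scrublet (in scanpy 1.11.5) marked 2 and 4 nuclei at its automatic threshold, under 0.5% of each library, so the rule fixed for that case was used: the highest-scoring share expected from loading (0.8% per 1000 nuclei) was removed, which was 298 and 71 nuclei. The final sets were 5809 and 2910 nuclei with 22336948 and 10606295 UMIs.

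Both libraries were clustered together without batch integration: counts scaled to 10000 per nucleus and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at a resolution of 1.0 with a fixed seed. Of 19 marker lists fixed in advance, 12 named the 21 clusters. A marker counted for a cluster at a level of 0.25 or more of its highest cluster level with UMIs in at least 5% and at least 5 of the nuclei, a name needed at least 3 such markers, and the highest mean level over the markers gave the name. This scoring was set after the files were read. Classes are called X-like because they rest on these markers. Classes with at least 50 nuclei in each library were compared, which gave 7 of the 12.

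Raw counts were summed per class and library and scaled to counts per 1000000 (CPM) of that sum. Each ratio is the deletion library over wild type, with an exact conditional binomial 95% interval; CPM values have exact Poisson intervals and shares have exact (Clopper-Pearson) binomial intervals. These intervals cover counting error only. Those on UMI counts treat each UMI as independent, also where many lie in the same nucleus. Since each group is 1 library, no test across animals was possible and none was made. A count of 0 was set to a floor of 3 counts in list medians and in the alternatives; a fold written as at least is the end of the exact interval nearest to 1. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with R 4.3.3 and edgeR 4.0.16 for the scaling alternative.

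Genes were named by a rule of size. A gene qualified within a class with at least 50 UMIs in 1 library, UMIs in at least 5% of the nuclei of the library with the higher level, a ratio of at least 2 either way and at least 2 the same way in the strained matrices. Genes were ranked by the bound of the counting interval nearest to 1, and the top 15 per direction were taken for myonucleus-like nuclei and the top 5 per direction for other classes. Predicted genes, mitochondrially encoded genes, ribosomal protein genes, Xist and Y-linked genes were not ranked. Dmd, Utrn, the 6 myosin heavy chains and the highest and lowest member of each list with at least 50 UMIs in 1 library were always named. Other list members in the text were picked as examples after their values were seen.

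There were 26 gene lists: in myonucleus-like nuclei, the dystrophin-associated complex, glycolysis and glycogen use, nuclear-encoded respiration, calcium handling, ubiquitin-proteasome and atrophy, autophagy and lysosome, denervation-responsive, developmental and regenerating-fibre, Z-disc stress and repair, slow-fibre and fast-fibre genes; in fibro-adipogenic progenitor-like nuclei, extracellular matrix, TGF-beta and fibrogenic signalling, and complement and cytokines; in macrophage-like nuclei, phagocytic and lipid-associated, resident-type, and inflammatory cytokine genes; in satellite cell-like nuclei, quiescence, and myogenic activation and differentiation; in endothelial-like nuclei, angiogenesis; and over all nuclei and each class, interferon response and MHC class I, cell cycle, immediate-early, mitochondrially encoded and haemoglobin genes, with X-inactivation and Y-linked genes as a label check over all nuclei. Members with at least 20 UMIs over both libraries were measured. The list value is the median log2 ratio with an order-statistic interval, set among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test. A median needed at least 3 measured members, a minimum set after values were seen. Members were counted as higher or lower at a ratio of 1.5 either way.

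The lists, marker names, rule for named genes, filters and most alternatives were fixed before the data were examined. The alternatives were at least 500 genes, at most 1% mitochondrial UMIs, no quality filter, no doublet removal, each library clustered on its own, Leiden resolutions of 0.5 and 2.0, the strained matrices, the mean over nuclei, thinning of each nucleus to 1000 UMIs, scaling by trimmed mean of M-values (TMM), and no minimum or 100 UMIs for list members. Alternatives added later were leaving out the myonuclear cluster led by repeat-like transcripts, using the Myh4-leading or the Myh1-leading clusters alone, and leaving out the myonucleus-like nuclei that held Myh7 UMIs. The level that free RNA would give a gene in a class was taken as the Ttn level of the class times the gene's level over that of Ttn in all nuclei.

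The counting steps were tested on simulated data made from the pooled profile of the myonucleus-like nuclei at the depths of both libraries. Of 50 genes each set to true folds of 0.25, 0.5, 2 and 4, the median estimates were 0.251, 0.499, 1.97 and 3.96, and 49, 48, 47 and 48 true folds lay inside their intervals. Among 7583 genes with no set difference, 95.9% of intervals held 1. The simulated sums were independent Poisson counts, the model that the intervals assume. They check the computation and not how the intervals hold where UMIs share a nucleus. Of 60 random lists of 15 genes, 4 had a percentile outside 2.5 to 97.5.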

Results

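RNA in single nuclei from the tibialis anterior, a muscle of the lower hindlimb, was counted in 2 libraries of 1-month-old C57BL6 mice. The groups were wild type and a deletion of exon 51 of Dmd, the gene of dystrophin, which links the cytoskeleton of the muscle fibre to the matrix around it. Each group had 1 library, so there are no replicates and no difference given here has a replicate check. The wild-type library held 7095 nuclei with 25068449 UMIs (median 2313 per nucleus) and the deletion library 4486 nuclei with 14096914 UMIs (median 1829). After filtering, 5809 wild-type and 2910 deletion nuclei remained, with medians of 2624 and 2325.5 UMIs. More than 5% of UMIs were mitochondrially encoded in 13.9% of wild-type nuclei and 33.5% of deletion nuclei, and these nuclei were left out. Levels are counts per 1000000 (CPM) of the summed raw counts of a class of nuclei; ratios are the deletion library over wild type. Brackets after a value hold its exact 95% counting interval, which covers counting error only. Brackets after a list median hold an interval of the median over its members, or their range in lists with fewer than 6.

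The first comparison concerned Dmd itself (ENSMUSG00000045103, GRCm38 chromosome X, 82948870 to 85206141, plus strand). Over all nuclei its level was 14195 CPM in wild type and 19178 CPM in the deletion library, a ratio of 1.35 (1.34 to 1.36). In myonucleus-like nuclei it was 15483 and 22988 CPM, a ratio of 1.48 (1.48 to 1.49), and in myoblast-like nuclei 5690 and 11663 CPM, a ratio of 2.05 (1.92 to 2.19). The ratio was 0.623 (0.574 to 0.675) in nuclei like fibro-adipogenic progenitors (FAPs), 0.698 (0.651 to 0.748) in satellite cell-like nuclei, 0.741 (0.649 to 0.844) in tenocyte-like nuclei, 0.793 (0.702 to 0.900) in macrophage-like nuclei and 0.938 (0.847 to 1.04) in endothelial-like nuclei. If all Ttn in a class came from free RNA, Dmd from that source would be 88.5% and 66.3% of the Dmd level in wild-type and deletion FAP-like nuclei, 84.4% and 89.2% in tenocyte-like, 71.9% and 97.8% in macrophage-like, 103% and 112% in endothelial-like and 35.6% and 57.1% in satellite cell-like nuclei. In myoblast-like nuclei it would be 162% and 144%, more than was measured, so part of the Ttn there is the nuclei's own and the share from free RNA is open. The ratios of the myoblast-like, FAP-like, tenocyte-like, macrophage-like and endothelial-like nuclei are therefore not read as a difference in Dmd expression. The ratios also depended on the processing: over the alternatives they went from 0.419 to 0.9752 in FAP-like, 0.326 to 0.821 in tenocyte-like, 0.338 to 1.10 in macrophage-like, 0.764 to 1.26 in endothelial-like and 0.542 to 1.00 in satellite cell-like nuclei. The targeted exon 51 spans 84474134 to 84474366 (233 bp), 728 kb before the last exon, exon 79. A 3′ tag outside the deleted part checks nothing about the deletion, so these levels neither show nor exclude it.

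Utrn, the gene of the dystrophin-related protein utrophin (chromosome 10, 12382188 to 12869365), was at 29.4 CPM in wild-type and 95.6 CPM in deletion myonucleus-like nuclei, a ratio of 3.25 (2.91 to 3.63), and over the alternatives the ratio went from 2.44 to 9.49. Over all nuclei, where the mix of classes differed between the libraries, the Utrn ratio was 1.88 (1.79 to 1.97). Myonucleus-like nuclei held 571 of 3549 wild-type and 750 of 3171 deletion Utrn UMIs. In each of the other 6 classes compared, the interval of the Utrn ratio included 1. Their wild-type Utrn levels were 313 to 1589 CPM, above the myonuclear one. Free RNA from those classes in myonucleus-like nuclei was not estimated.

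The second comparison concerned which classes of nuclei the muscles gave. Macrophage-like nuclei made up 0.947% (0.714 to 1.23) of wild-type nuclei and 7.46% (6.53 to 8.47) of deletion nuclei, a ratio of 7.88 (5.83 to 10.8). FAP-like nuclei, from the cells that lay down connective tissue, made up 5.42% (4.85 to 6.04) and 13.2% (12.0 to 14.5), a ratio of 2.44 (2.10 to 2.84). Regenerating myonucleus-like nuclei, defined here by embryonic and neonatal myosin and related markers, made up 4.91% (4.16 to 5.76) of deletion nuclei. None of the 5809 wild-type nuclei fell in that class, with an interval up to 0.0635%, so the share was at least 76.4-fold higher in the deletion library. Myonucleus-like nuclei made up 73.0% (71.8 to 74.1) of wild-type nuclei, and 1746 of 2910 deletion nuclei were in that class, with an interval of 58.2 to 61.8%; the ratio was 0.822 (0.777 to 0.870).

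Vessel-related classes had lower shares in the deletion library. Endothelial-like nuclei made up 5.94% (5.34 to 6.58) of wild-type and 1.96% (1.49 to 2.53) of deletion nuclei, 3.03-fold lower (2.29 to 4.09). Smooth muscle or pericyte-like nuclei made up 4.10% and 0.893%, 4.59-fold lower (3.05 to 7.16), but the ratio was 1.57 when each library was clustered on its own. Schwann cell-like nuclei, 42 and 6 in number, were 3.51-fold lower (1.48 to 10.1), and their ratio was 0.998 without the quality filter. Myotendinous junction-like nuclei made up 0.689% and 1.41%, a ratio of 2.05 (1.29 to 3.25). Shares of satellite cell-like (3.94% and 4.16%), myoblast-like (2.10% and 2.47%), tenocyte-like (2.51% and 2.58%) and neuromuscular junction-like nuclei (0.654% and 0.722%) had ratios of 1.05 (0.839 to 1.32), 1.18 (0.868 to 1.59), 1.03 (0.766 to 1.36) and 1.10 (0.615 to 1.93).

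Several of these shares depended on the filter on mitochondrial UMIs, which removed more of the deletion library. With at most 1% mitochondrial UMIs the FAP ratio was 1.28, the endothelial ratio 0.0971 from 1 deletion nucleus and the neuromuscular junction ratio 2.17, while the tenocyte ratio was 0.455 with at least 500 genes, 0.648 with separate clustering, and the macrophage ratio 12.1 without a quality filter. The Hoechst sort, the lower depth of the deletion library and the use of 1 library per group can each set shares, and a share of nuclei is not a number of cells in the muscle.

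**Figure D1:**
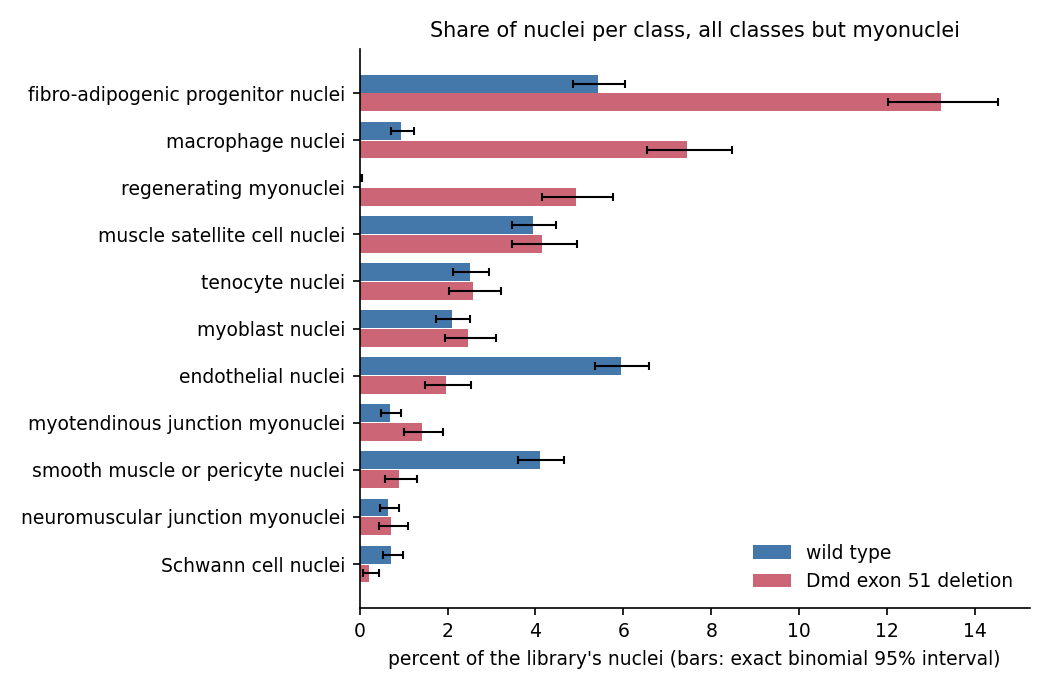
Share of nuclei (percent of the library) in each class but the myonucleus-like one, in the wild-type and deletion libraries, with exact binomial 95% intervals for counting error. Macrophage-like nuclei were at 0.947% and 7.46%, and endothelial-like nuclei at 5.94% and 1.96%.

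The third comparison concerned fibre type, read from myosin heavy chain genes over all myonuclear classes. Myh4, the chain of the fastest (2B) fibres, took 37.8% (37.5 to 38.1) of 138529 heavy chain UMIs in wild type and 50.7% (50.2 to 51.2) of 41464 in the deletion library. Myh1, the 2X chain, took 48.5% (48.2 to 48.8) and 39.2% (38.7 to 39.7), and Myh2, the 2A chain, 13.7% (13.5 to 13.8) and 6.44% (6.20 to 6.68). The chains with the smallest shares were all higher in the deletion library. Slow Myh7 took 0.0195% and 0.552%, embryonic Myh3 0.00577% and 2.0%, and neonatal Myh8 0.0253% and 1.14%. The 5 genes other than Myh7 lie together on chromosome 11 between 67078300 and 67308634, and reads shared between such close paralogs were not examined. The Myh4 difference was 12.9 percentage points, and 35.7 with at most 1% mitochondrial UMIs.

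**Figure D2:**
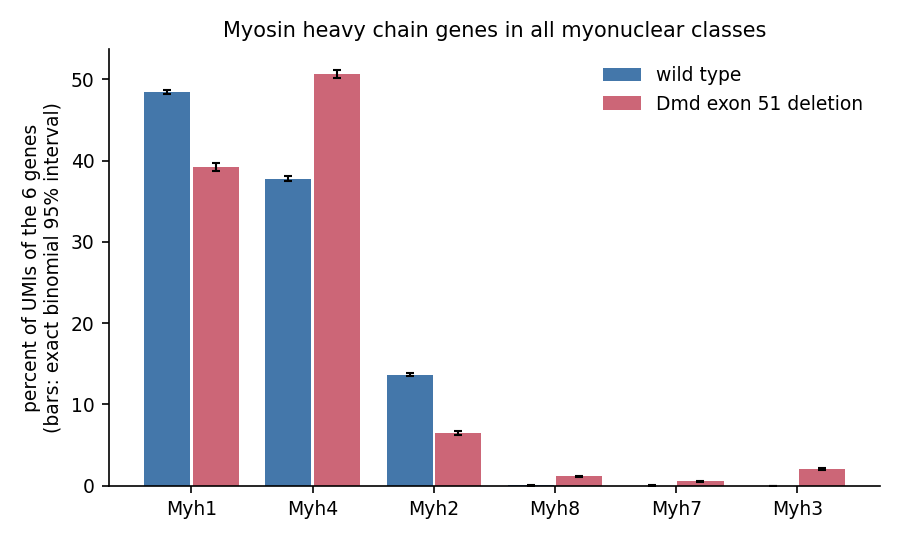
Share of each of 6 myosin heavy chain genes among their summed UMIs (percent) over all myonuclear classes of each library, with exact binomial 95% intervals for counting error. Myh4 was at 37.8% in wild type and 50.7% in the deletion library.

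Within myonucleus-like nuclei, leaving out the regenerating and junction classes, Myh1 was at 3429 and 1918 CPM, a ratio of 0.559 (0.550 to 0.569), and Myh2 at 964 and 328 CPM, a ratio of 0.340 (0.326 to 0.354). Both depended on the mix of clusters: Myh1 was at 0.844 in the Myh4-leading and 0.728 in the Myh1-leading clusters and Myh2 at 0.626 and 0.469, and over the alternatives they were lowest at 0.367 and 0.281. Myh4 was at 2670 and 2590 CPM, a ratio of 0.970 (0.955 to 0.986) that turned to 1.69 with at most 1% mitochondrial UMIs and to 1.38 in the Myh1-leading clusters alone. Myh7 was at 1.39 and 28.8 CPM, a ratio of 20.7 (13.9 to 32.1), but its UMIs came from 3 of 4239 wild-type and 8 of 1746 deletion nuclei, with 159 of 226 deletion UMIs in a single nucleus. Myh8 was at 1.80 and 8.92 CPM, a ratio of 4.95 (3.25 to 7.65). Over the alternatives Myh7 went from 16.7 to 35.2 and Myh8 from 2.93 to 8.64. Myh3, with 5 and 34 UMIs, had a ratio of 16.8 (6.54 to 55.1) that turned to 0.854 in the strained matrices.

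The main comparison concerned gene expression in myonucleus-like nuclei, 4239 in wild type and 1746 in the deletion library, with medians of 3389 and 3267 UMIs. Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149), a transcription factor induced in denervated muscle, was at 6.39 CPM in wild type and 164 CPM in the deletion library, 25.7-fold higher (21.3 to 31.1). Igfn1 (chromosome 1, 135953578 to 136006342), of a muscle Z-disc protein, was at 6.34 and 133 CPM, 21.0-fold higher (17.4 to 25.5). The transcription factor gene Glis3 was at 4.59 and 85.3 CPM, 18.6-fold higher (14.9 to 23.5). Ncam1, of an adhesion molecule that reappears on denervated and regenerating fibres, was at 11.5 and 95.3 CPM, 8.26-fold higher (7.11 to 9.63). Atp2a2, of the slow-fibre calcium pump, was at 6.13 and 41.8 CPM, 6.82-fold higher (5.51 to 8.48).

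In this direction the rule of size also named, with ratios in brackets, Cyfip2 (14.4), Dclk1 (11.7), Cers6 (7.70), Map1b (7.59) and Arhgap18 (7.10). It further named Cdk6 (6.97), Cd44 (6.73), Ddr2 (6.46), Eda2r (6.04) and Cdk14 (5.46). Genes with UMIs in under 5% of nuclei, such as Myh7, could not qualify. Cdk14 had the highest level of the 15, 49.0 and 268 CPM. The sizes of most depended on the processing, and none changed direction. Over the alternatives the lowest and highest ratios were 10.3 and 63.1 for Igfn1, 12.6 and 32.9 for Glis3, 3.69 and 35.6 for Cyfip2 (in Myh4-leading and Myh1-leading clusters), 6.94 and 27.5 for Dclk1, 3.23 and 21.9 for Ddr2, 2.35 and 8.70 for Cers6, 2.45 and 8.56 for Cdk6, 4.86 and 12.4 for Map1b and 4.94 and 12.2 for Arhgap18. Atp2a2 was at 13.1 with at most 1% mitochondrial UMIs and at 2.78 without the nuclei that held Myh7 UMIs.

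Among the genes lower in the deletion library, Socs2, of an inhibitor of growth hormone signalling, was at 34.3 and 4.72 CPM, 7.27-fold lower (5.22 to 10.4). Tnni2, of fast troponin I, was at 415 and 110 CPM, 3.77-fold lower (3.51 to 4.05), and Actg1, of cytoplasmic gamma actin, at 534 and 146 CPM, 3.66-fold lower (3.44 to 3.89). G0s2, of an inhibitor of fat breakdown, was at 68.4 and 16.2 CPM, 4.22-fold lower (3.52 to 5.11), and Lamb2, of a laminin chain, at 56.1 and 13.8 CPM, 4.08-fold lower (3.34 to 5.01). Others were Doc2g (6.22-fold lower), Epo (6.17), Sntg2 (4.78), Abca2 (4.50), Ybx2 (4.49), Atp5d (4.28), Mcrip2 (4.15), Evc (4.12) and Tmem52 (3.94). Epo and Doc2g overlap other protein-coding genes on their own strand, so their counts are uncertain. Over the alternatives Socs2 went from 4.85-fold to 12.9-fold lower, Sntg2 from 2.56 to 5.30, Evc from 3.08 to 8.78 Atp5d from 3.99 to 7.36, Abca2 from 3.24 to 6.89 and Tmem52 from 3.38 to 6.18.

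Different clusters held most of the class in each library. Clusters 0, 1, 2, 3 and 8 held 1465, 794, 779, 661 and 297 wild-type nuclei against 98, 167, 100, 46 and 56 deletion nuclei, while clusters 4 and 6 held 54 wild-type nuclei each against 630 and 494 deletion nuclei. Cluster 10, led by repeat-like transcripts, held 135 and 155. Igfn1, Eda2r and Arhgap18 were among the leading genes of cluster 4, Cyfip2 of cluster 6, Sntg2 of cluster 0, Ybx2 of cluster 3 and G0s2 of cluster 8, so these genes also shaped the clusters, and a cluster mostly of 1 library may be that library and not a kind of fibre. Dclk1 and Ncam1 were among the leading genes of the regenerating cluster, outside this class, which held 0 wild-type and 143 deletion nuclei. Free RNA or misplaced nuclei from that cluster were not examined.

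Gene lists fixed in advance gave a broader view of the same nuclei, and list members named besides the highest and lowest were chosen after their values were seen. Slow-fibre genes were the list with the highest median log2 ratio, 2.70 (-1.61 to 4.17), and 8 of 10 members were at least 1.5-fold higher and 2 lower. Tnnt1, of slow troponin T, was at 0.721 and 9.81 CPM, a ratio of 13.6 (7.64 to 26.0), while Myl3, of a slow light chain, was at 7.32 and 1.66 CPM, 4.42-fold lower. Few nuclei carried this: Tnnt1 UMIs were in 6 wild-type and 21 deletion nuclei, and without the 3 and 8 nuclei that held Myh7 UMIs the list's median turned to -0.90 over 6 members. It was 1.58 with at least 100 UMIs per member, 1.19 after thinning and 0.91 in the Myh4-leading clusters. Fast-fibre genes had a median of -0.39 (-1.09 to 0.00), with 5 of 13 members at least 1.5-fold lower and none as much higher; Tnnt3, of fast troponin T, was at 2107 and 1145 CPM, a ratio of 0.543 (0.531 to 0.556), and Myl1 was highest at 1.31 (1.28 to 1.33). With at most 1% mitochondrial UMIs the fast-fibre median was 0.00.

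Genes known to respond to denervation had a median of 1.00 (-0.06 to 3.05), with 6 of 10 members at least 1.5-fold higher and 1 lower. Besides Runx1 and Ncam1, Musk, of the kinase that organises the neuromuscular junction, was at 32.5 and 80.0 CPM, a ratio of 2.47 (2.20 to 2.76), while the transcription cofactor gene Dach2 was at 33.2 and 12.2 CPM, 2.72-fold lower. This median was -0.01 within the Myh1-leading clusters. Developmental and regenerating-fibre genes had a median of 1.5 (-1.13 to 4.07), with 5 of 7 members at least 1.5-fold higher, and 0.18 in the strained matrices. Actc1, of cardiac alpha actin, was the lowest member at 59.6 and 27.3 CPM, 2.18-fold lower.

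Some genes of protein breakdown were higher. In the ubiquitin-proteasome and atrophy list, with a median of 0.17 (-0.28 to 0.51), 3 of 16 members were at least 1.5-fold higher and 1 lower. The muscle ubiquitin ligase genes Fbxo32 (204 and 519 CPM) and Trim63 (280 and 557 CPM) had ratios of 2.54 (2.43 to 2.65) and 1.99 (1.91 to 2.07). The autophagy and lysosome list had a median of 0.25 (0.02 to 0.81), with 4 of 13 members at least 1.5-fold higher and none as much lower. Bnip3, of a mitophagy receptor, was at 38.0 and 83.4 CPM, a ratio of 2.20 (1.97 to 2.44), and Tfeb was lowest at 0.845 (0.793 to 0.899).

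In the dystrophin-associated complex, with a median of 0.18 (-0.02 to 1.12), 4 of 15 members were at least 1.5-fold higher and 2 lower. Besides Utrn, Lama2, of the laminin chain that the complex binds, was at 115 and 335 CPM, a ratio of 2.92 (2.76 to 3.09). The syntrophin gene Sntb1 was at 41.7 and 90.5 CPM, a ratio of 2.17 (1.96 to 2.40). Free RNA from other classes was not estimated for any gene in myonucleus-like nuclei. Sgca, of alpha sarcoglycan, was at 90.2 and 46.8 CPM, 1.93-fold lower, and Nos1, of neuronal nitric oxide synthase, at 211 and 131 CPM, 1.61-fold lower. The Z-disc stress and repair list had a median of -0.03 (-0.33 to 0.63). In it the stretch-responsive Ankrd1 was at 1.70 and 14.7 CPM, a ratio of 8.62 (5.81 to 13.1), Nrap had a ratio of 1.66 (1.61 to 1.71), and the small heat shock protein gene Hspb1 was 2.07-fold lower. Calcium handling genes had a median of -0.16 (-0.29 to 0.17), with 13 of 15 members within 1.5-fold either way; Atp2a2 was highest and Casq2, of cardiac calsequestrin, was at 162 and 53.0 CPM, 3.05-fold lower.

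The nuclear-encoded respiration list and the glycolysis and glycogen list both had negative medians. All 15 measured nuclear-encoded respiration genes were lower, 3 of them at least 1.5-fold, with a median of -0.48 (-0.58 to -0.24). Cox7a1 was lowest at 4.90 and 2.04 CPM, 2.40-fold lower, and Ndufa9 was nearest to equal at 0.929 (0.790 to 1.09). Glycolysis and glycogen genes had a median of -0.22 (-0.44 to 0.01), with 3 of 17 members at least 1.5-fold lower and none as much higher, and the median was -0.04 with at most 1% mitochondrial UMIs. Aldoa was at 367 and 208 CPM, 1.77-fold lower, and Phka1, of a phosphorylase kinase subunit, was highest at 1.44 (1.42 to 1.47). Mitochondrially encoded genes went the other way, with all 10 at least 1.5-fold higher and a median of 0.81 (0.64 to 0.87), though over all nuclei their median turned to -1.08 in the strained matrices.

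Ratios also varied with the genomic span of the gene in these nuclei. The median log2 ratio was -0.52 in the 10% of genes with the shortest spans (median 3.34 kb) and 0.22 in the 10% with the longest (median 274 kb). Respiration genes had a median span of 16.5 kb. The ratios of the genes named in these nuclei are not corrected for span. Among them the lower genes G0s2, Tnni2 and Actg1 have short spans, though Sntg2 does not, and the higher genes Runx1, Glis3 and Cdk14 have long ones. Among 10000 random lists matched on expression, the respiration, glycolysis and fast-fibre medians were at percentiles 0, 1.02 and 0.06; among lists matched also on span they were at 3.63, 16.5 and 5.7. The calcium list was at 3.2 and then 4.2, the ubiquitin list at 88.5 and 97.0, the autophagy list at 97.0 and 98.7, the dystrophin complex at 87.9 and 88.6, the Z-disc list at 31.7 and 73.6, and the slow-fibre, denervation and developmental lists at 100 both ways. These percentiles describe the spread of genes within these libraries and are not a test between genotypes. The same trend with span was present in each of the other 6 classes compared, where medians in the shortest 10% and the longest 10% were -0.45 and 0.08 in FAP-like, -0.20 and 0.05 in macrophage-like, -0.38 and 0.25 in satellite cell-like, -0.66 and 0.16 in myoblast-like, -0.50 and 0.10 in tenocyte-like and -0.51 and 0.19 in endothelial-like nuclei; the ratios and list medians of those classes are not corrected for it.

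**Figure D3:**
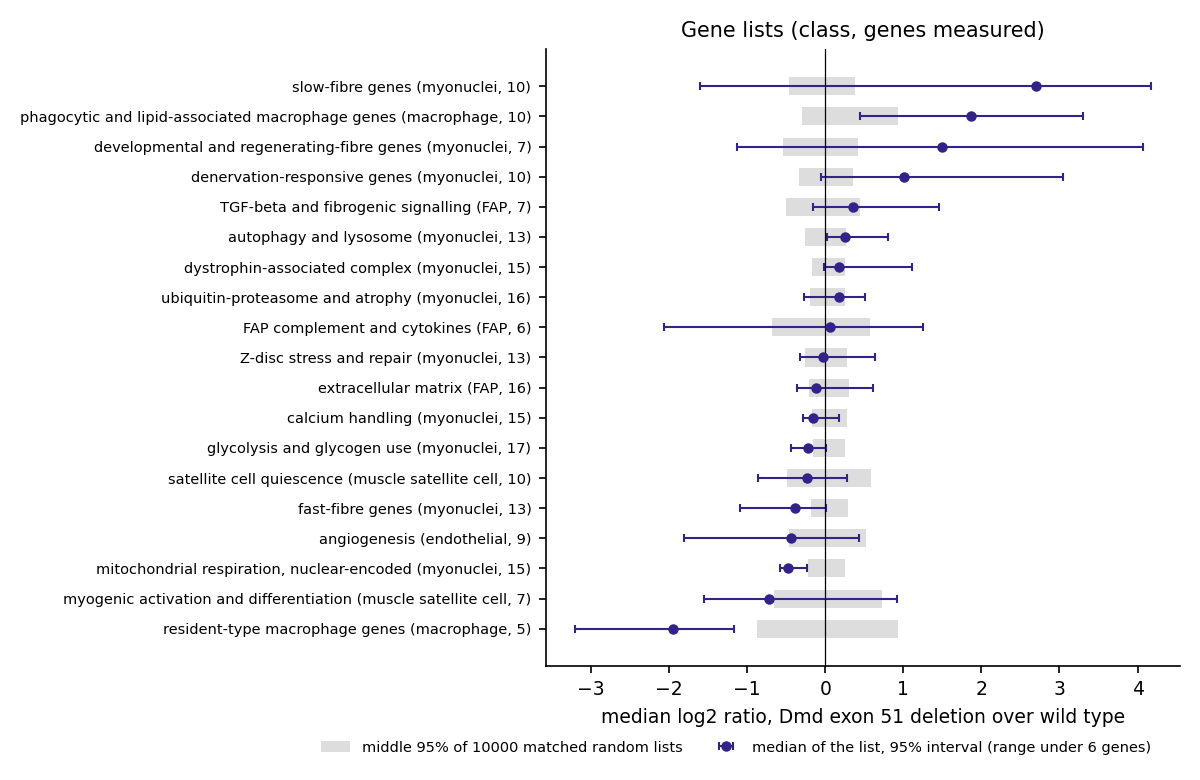
Median log2 ratio (deletion over wild type) of each gene list in the class it was fixed for, with the interval of the median (the range in lists with fewer than 6 genes) and the middle 95% of matched random lists. Slow-fibre genes were at 2.70 and nuclear-encoded respiration genes at -0.48 in myonucleus-like nuclei.

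**Figure D4:**
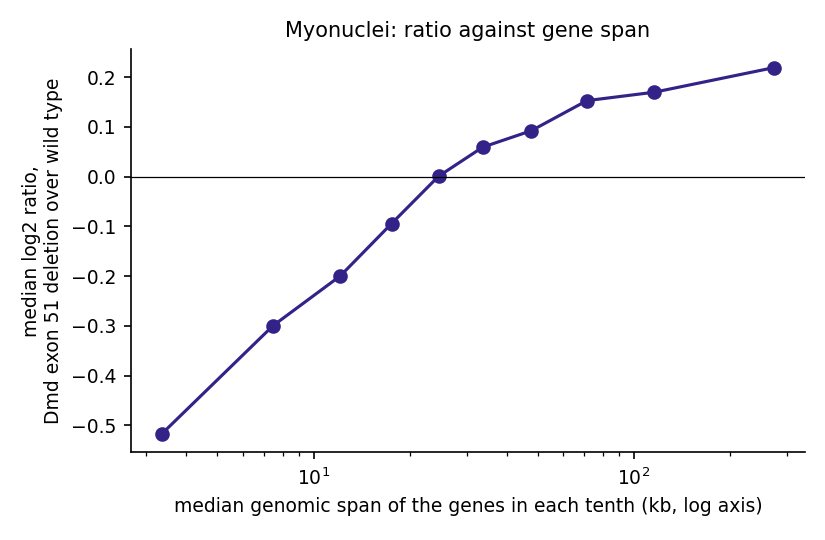
Median log2 ratio in myonucleus-like nuclei against median genomic span (kb, log axis) for genes in 10 groups of rising span. The points go from -0.52 at 3.34 kb to 0.22 at 274 kb.

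In FAP-like nuclei (315 and 385), Postn, of the matrix protein periostin, was at 84.5 and 735 CPM, 8.70-fold higher (6.49 to 11.9). The class joined cluster 5, with 253 wild-type and 355 deletion nuclei, and cluster 16, with 62 and 30. This mix differed between the libraries, and the ratios and list medians of the class are not adjusted for it. Tnc, of tenascin C, was at 17.2 and 247 CPM, 14.3-fold higher (7.62 to 30.4), with UMIs in 1.27% and 5.19% of nuclei. Runx1 was at 19.0 and 271 CPM, 14.3-fold higher (7.80 to 29.1), the guidance gene Slit2 14.1-fold (6.26 to 39.2) and Edil3 15.5-fold higher (5.83 to 58.4). Vegfa, of the main vessel growth factor, was at 540 and 97.53 CPM, 5.53-fold lower (4.26 to 7.26), and Adamtsl2 at 121 and 8.24 CPM, 14.6-fold lower (6.40 to 41.3). Mlxipl was 9.41-fold lower (4.48 to 22.8). Over the alternatives the ratio went from 7.08 to 20.2 for Runx1, 6.42 to 32.9 for Slit2 and 5.18 to 33.1 for Edil3, Vegfa from 3.90-fold to 18.7-fold lower, Adamtsl2 from 9.03-fold to 28.3-fold and Mlxipl from 4.37-fold to 14.3-fold lower. The fibre genes Ttn and Myh2 were 5.15-fold (4.86 to 5.46) and 11.1-fold (6.51 to 20.4) lower in this class, and from 2.30-fold to 8.52-fold and 3.59-fold to 48.5-fold over the alternatives. As a measure of free RNA, Ttn in FAP-like nuclei was at 13.4% of its myonuclear level in wild type and 4.16% in the deletion library. Free RNA at these shares would give 72.5% and 103% of the Mlxipl level and 43.5% and 28.3% of the Vegfa level in this class. For the fibre gene Myh2 it would give 55.4% and 63.2%, so this measure can fall short of the free RNA present. Neither Mlxipl nor Vegfa is therefore read as a difference in FAP expression.

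The extracellular matrix list as a whole had a median of -0.11 (-0.36 to 0.61) in FAP-like nuclei, at percentile 8.31, with 5 of 16 members at least 1.5-fold higher and 2 lower. Fn1, of fibronectin, was at 141 and 341 CPM, a ratio of 2.41 (1.87 to 3.13), while the fibrillar collagen genes Col1a1 and Col3a1 had ratios of 0.920 (0.802 to 1.06) and 0.820 (0.761 to 0.885), and Col6a1 was lowest at 0.565 (0.436 to 0.728). TGF-beta and fibrogenic signalling genes had a median of 0.36 (-0.16 to 1.45), at percentile 94.4, with 3 of 7 measured members at least 1.5-fold higher. Tgfb2 was at 87.9 and 162 CPM, a ratio of 1.84 (1.32 to 2.61), and Ltbp1 was lowest at 0.896 (0.702 to 1.14). The complement and cytokine list had a median of 0.06 over 6 of 13 members, at percentile 64.6, and C1s1 had a ratio of 1.06 (0.773 to 1.45).

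In macrophage-like nuclei (55 and 217), genes of lipid-loaded phagocytes were higher and genes of resident-type macrophages lower in the deletion library. Gpnmb had 0 and 233 UMIs (0 and 521 CPM), at least 8.24-fold higher, and Lgals3, of galectin-3, 0 and 225 UMIs, at least 7.96-fold higher. Mamdc2 was at least 5.03-fold higher. Atp6v0d2, of a proton pump subunit, had 1 and 351 UMIs, a ratio of 46.2 (8.23 to 1828), and St18 had 3 and 361 UMIs, a ratio of 15.8 (5.37 to 77.1); over the alternatives Atp6v0d2 went from 30.5 to 71.4 and, with the count of 0 set to 3, Gpnmb from 8.89 to 28.0. Atp6v0d2 and St18 were also among the leading genes of the macrophage cluster, of which 79.8% came from the deletion library. The phagocytic list had a median of 1.87 (0.44 to 3.30), at percentile 100, with 8 of 10 measured members at least 1.5-fold higher and none as much lower, where a count of 0 was set to 3. Spp1, of osteopontin, had 0 and 68 UMIs, at least 2.36-fold higher, and Apoe was lowest at 0.877 (0.583 to 1.37).

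All 5 measured resident-type macrophage genes were at least 1.5-fold lower, with a median of -1.95 (-3.21 to -1.17) at percentile 0. Mrc1, of the mannose receptor, was at 1939 and 651 CPM, 2.98-fold lower (2.38 to 3.71), F13a1 at 1786 and 463 CPM, 3.86-fold lower (3.02 to 4.90), and Cd163 at 476 and 51.5 CPM, 9.26-fold lower. Maf was nearest to equal, 2.25-fold lower. Mctp1 (3913 and 837 CPM) was 4.68-fold lower (3.95 to 5.53) and the scavenger receptor gene Stab1 3.35-fold lower (2.43 to 4.58). The muscle calcium pump gene Atp2a1 was 3.59-fold lower (2.79 to 4.61) here, and from 2.69-fold to 6.003-fold over the alternatives, but Ttn in this class was at 23.3% and 16.8% of its myonuclear level, and free RNA at these shares would give 51.2% and 98.3% of its level. Of the 11 inflammatory cytokine and receptor genes only 1 was measured, so that list has no median. TMM scaling would raise all log2 ratios of this class by 0.35.

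In satellite cell-like nuclei, the muscle stem cells (229 and 121), Runx1 was at 117 and 3290 CPM, 28.0-fold higher (20.3 to 39.9). Hmga2, of a chromatin protein of proliferating stem cells, had 0 and 190 UMIs, at least 61.9-fold higher by UMI counts. The 190 UMIs came from 12.4% of the deletion nuclei, and the interval does not allow for UMIs that share a nucleus. Adgrl3 was at 52.5 and 899 CPM, 17.1-fold higher (10.5 to 29.9), and Col8a1 at 12.3 and 367 CPM, 29.7-fold higher (11.3 to 111). Tnc had 2 and 53 UMIs, a ratio of 32.2 (8.48 to 273). Pde10a, of a cyclic nucleotide phosphodiesterase, was at 3679 and 438 CPM, 8.39-fold lower (6.94 to 10.2), and Clmn at 735 and 52.5 CPM, 14.0-fold lower (8.18 to 26.0). Pgm5 was 10.6-fold lower (6.02 to 20.3) and Erfe 12.97-fold lower (4.82 to 49.1), and Ttyh1, with 64 and 0 UMIs, at least 13.9-fold lower. Over the alternatives the ratio went from 14.5 to 30.3 for Runx1, 15.4 to 38.9 for Adgrl3, 17.3 to 41.7 for Col8a1 and 7.19 to 42.3 for Tnc. Pgm5 went from 3.95-fold to 15.3-fold lower, Clmn from 6.52-fold to 18.0-fold and Erfe from 7.53-fold to 16.1-fold lower. With the count of 0 set to 3, Hmga2 was at 76.9 as reported and at 12.0 after thinning, and Ttyh1 17.6-fold and 4.82-fold lower.

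The quiescence list in these nuclei had a median of -0.24 (-0.87 to 0.28), at percentile 13.1, with 4 of 10 members at least 1.5-fold lower and 1 higher. Pax7, the marker transcription factor of satellite cells, was at 920 and 678 CPM, a ratio of 0.737 (0.610 to 0.890), Chrdl2 was 8.38-fold lower and Notch3 had a ratio of 1.09 (0.864 to 1.37). Myogenic activation and differentiation genes had a median of -0.72 (-1.56 to 0.91), at percentile 1.8, with 4 of 7 measured members at least 1.5-fold lower, and -0.12 after thinning. Megf10 was at 466 and 277 CPM, 1.68-fold lower, and Mef2a had a ratio of 1.88 (1.37 to 2.60). Cell cycle genes in this class had a median of 0.54 (-0.33 to 1.78), and Mki67, Top2a and Cenpf were among the leading genes of the satellite cell cluster in both libraries together.

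In myoblast-like nuclei (122 and 72), the largest ratios were smaller. The adhesion gene Ncam1 was at 124 and 353 CPM, 2.85-fold higher (1.85 to 4.45), and Arhgap6 2.88-fold (2.20 to 3.80), Ppp1r14c 3.41-fold (2.10 to 5.65) and Rnf150 2.63-fold higher (1.88 to 3.69). Cdkn1c, of a cell cycle inhibitor and also a leading gene of this cluster, was at 351 and 73.0 CPM, 4.80-fold lower (2.63 to 9.60), and the growth-restraining RNA H19 at 1186 and 377 CPM, 3.14-fold lower (2.39 to 4.19). Brd1, Aldoa and Slc29a1 were 4.99-fold, 3.82-fold and 4.52-fold lower. Over the alternatives the ratio went from 1.79 to 3.67 for Arhgap6, 1.41 to 3.06 for Rnf150 and 2.70 to 5.14 for Ncam1, and Cdkn1c went from 3.14-fold to 12.9-fold, Slc29a1 from 2.24-fold to 4.58-fold and Brd1 from 1.58-fold to 4.95-fold lower. Ttn in this class was at 58.9% and 71.7% of its myonuclear level. If all of it came from free RNA, that source would give 221% and 116% of the Arhgap6 level, 135% and 81.0% for Ppp1r14c, 265% and 163% for Rnf150, 27.7% and 98.9% for Ncam1, 74.2% and 194% for Aldoa and 24.5% and 163% for Brd1, so these ratios are not read as a difference in myoblast expression.

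In tenocyte-like nuclei (146 and 75), Runx2, of a transcription factor of bone formation, was at 134 and 1346 CPM, 10.1-fold higher (7.46 to 13.8). Zeb2 was 9.61-fold (6.40 to 14.8) and Edil3 8.84-fold (6.27 to 12.7) higher, and Slit2 (13.9) and Efna5 (9.62) were also among the highest. All of these depended on the clustering: with each library clustered on its own the ratios were 2.86 for Runx2, 3.76 for Zeb2, 5.499 for Edil3, 1.03 for Slit2 and 0.202 for Efna5. Eln, of elastin, had 114 and 0 UMIs, at least 11.3-fold lower (with the count of 0 set to 3, from 4.57-fold to 31.6-fold over the alternatives), and Cercam was 8.57-fold lower (4.43 to 19.0), or 5.203-fold with separate clustering. Angptl7, Myo7a and Grm7 had 1, 1 and 2 UMIs in the deletion library and were 46.2-fold (8.14 to 1839), 27.6-fold (4.80 to 1104) and 14.0-fold (3.74 to 117) lower, and at the least 3.98-fold, 7.52-fold and 5.28-fold lower over the alternatives.

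In endothelial-like nuclei (345 and 57), Vegfc, of a growth factor of lymph vessels, was at 243 and 1071 CPM, 4.40-fold higher (3.31 to 5.84). Dnm3, Zfp521, Thsd7a and Arhgap26 had ratios of 2.43, 2.45, 2.42 and 2.02. Vegfc was at 2.93 with each nucleus given the same weight and Arhgap26 at 1.34 without a quality filter. The angiogenesis list had a median of -0.44 (-1.81 to 0.44), at percentile 3.05, with 4 of 9 members at least 1.5-fold lower and 1 higher. The vessel growth factor receptor gene Flt1 was at 1230 and 671 CPM, a ratio of 0.545 (0.403 to 0.723), Tie1 was lowest at 0.280 (0.0749 to 0.740) and Vwf highest at 1.67 (0.970 to 2.74). Timp4 had 102 and 1 UMIs, 14.6-fold lower (2.56 to 581), and from 7.91-fold to 35.6-fold over the alternatives. Ky, Rcan2 and Dot1l had none in the deletion library, at least 3.26-fold, 3.18-fold and 2.87-fold lower (1.51-fold, 2.12-fold and 1.96-fold at the least over the alternatives), but free RNA at the Ttn share would give 87.2%, 99.2% and 72.0% of their wild-type levels, so they are not read as a difference in endothelial expression. The fast-fibre gene Tnni2 had 146 and 1 UMIs in this class, 20.8-fold lower (3.68 to 829) and from 5.16-fold to 102-fold over the alternatives, where free RNA at that share would give 62.3% of the wild-type level, and Ttn was at 39.7% and 27.1% of its myonuclear level. TMM scaling would lower all log2 ratios here by 0.30, and the deletion library had 77531 UMIs in this class.

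Over all nuclei, where the mix of classes differed between the libraries, cell cycle genes had a median of 0.90 (0.39 to 1.34), at percentile 99.8, with 7 of 12 members at least 1.5-fold higher. Top2a was at 6.58 and 14.5 CPM, a ratio of 2.21 (1.75 to 2.79), and Cenpf was at 1.31 (1.01 to 1.70). The median was -0.01 after thinning and 1.45 with at most 1% mitochondrial UMIs. Interferon response and MHC class I genes had a median of 0.49 (0.13 to 1.02), at percentile 93.1, with 4 of 9 members at least 1.5-fold higher. B2m was at 5.64 and 13.4 CPM, a ratio of 2.37 (1.85 to 3.04). The interferon median was 0.87 in myonucleus-like nuclei, and over all nuclei it was 1.03 with at most 1% mitochondrial UMIs and -0.00 with each nucleus given the same weight. Mitochondrially encoded genes had a median of 0.71 (0.53 to 0.77) over all nuclei, which was 0.25 with at most 1% mitochondrial UMIs, 1.65 without a quality filter and -1.08 in the strained matrices. TMM scaling would lower all log2 ratios over all nuclei by 0.16.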

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

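The alternatives that use the Myh4-leading clusters, the Myh1-leading clusters, all but the repeat-rich cluster or all but the nuclei holding Myh7 were added after the data were seen, as were the minimums of 50 nuclei per class and of 20 UMIs per list member within alternatives, of 3 members for a median, and the rule of no ratio where both counts are at or under 3. Over the alternatives, 335 list medians stayed inside the interval of the reported value, 10 moved outside and 5 reversed. That interval is taken over the members of the list and can be wide, as for slow-fibre genes (-1.61 to 4.17). A median inside it can still have moved far, so these counts do not compare with those of the CPM ratios. Of the share ratios, 56 stayed, 15 moved and 1 reversed; of the CPM ratios of named genes, 954 stayed, 214 moved and 7 reversed; of the heavy chain shares, 17 stayed and 13 moved. Where nothing else is said, the cause was not tested. Values in this part are ratios of the deletion library over wild type, heavy chain differences in percentage points (12.9 for Myh4 as reported) or median log2 ratios over all nuclei, and Dmd is given in myonucleus-like nuclei unless a class is named.

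Without a quality filter the share ratios were 0.998 for Schwann cell-like, 12.1 for macrophage-like, 1.64 for myoblast-like and 0.755 for myonucleus-like nuclei, the share of regenerating nuclei in the deletion library was 4.14%, the Myh4 difference was 11.5, Dmd was at 1.45, and the medians were 1.34 for cell cycle, 1.65 for mitochondrially encoded and -2.59 for haemoglobin genes. With at most 1% mitochondrial UMIs the share ratios were 0.0971 for endothelial-like, 1.28 for FAP-like, 0.694 for myonucleus-like and 2.17 for neuromuscular junction-like nuclei, the Myh4 difference was 35.7, Dmd was at 1.5, Myh4 in myonucleus-like nuclei reversed to 1.69, the fast-fibre median reversed to 0.0045, and the medians were 1.03 for interferon, 1.45 for cell cycle and 0.25 for mitochondrially encoded genes, the last by construction. With at least 500 genes the share ratio was 11.2 for macrophage-like and 0.455 for tenocyte-like nuclei.

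With each library clustered on its own the share ratios were 1.35 for satellite cell-like, 0.756 for myonucleus-like and 0.648 for tenocyte-like nuclei and reversed to 1.57 for smooth muscle or pericyte-like nuclei; the regenerating share was 6.67%, the Myh4 difference 12.2, Dmd 1.49, and Efna5 in tenocyte-like nuclei reversed to 0.202. With the mean over nuclei the Myh4 difference was 9.45, Dmd 1.53, and the medians -0.0044 for interferon and 0.52 for mitochondrially encoded genes. After thinning the Myh4 difference was 9.61, Dmd 1.58, and the medians 0.48 for mitochondrially encoded and, reversed, -0.0090 for cell cycle genes. In the strained matrices Dmd was at 1.53, Myh3 reversed to 0.854 and the mitochondrially encoded median to -1.08. With TMM scaling Dmd was at 1.41, the haemoglobin median at -1.41, and Dmd in macrophage-like nuclei reversed to 1.01, by a shift common to all genes; it also reversed without doublet removal, to 1.10. At a Leiden resolution of 0.5, Dmd in satellite cell-like nuclei was at 1.00. In the Myh4-leading clusters Dmd was at 1.59, and in the Myh1-leading clusters at 1.37, where Myh4 reversed to 1.38 and the denervation median to -0.0089. Without the 3 wild-type and 8 deletion nuclei holding Myh7, the slow-fibre median reversed from 2.70 to -0.90, so those nuclei carried it.

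Classes with few nuclei gave no value under some alternatives: expression with at most 1% mitochondrial UMIs was available for myonucleus-like nuclei and for all nuclei together alone, and macrophage-like and endothelial-like expression had none after thinning or with at least 500 genes, which also left none for myoblast-like and tenocyte-like expression. Myoblast-like expression had none at either Leiden resolution or with separate clustering. Shares with at most 1% mitochondrial UMIs had no value for classes other than the endothelial-like, FAP-like, myonucleus-like and junction ones, and the Schwann cell-like share had none without doublet removal, with separate clustering or with at least 500 genes. Depth limits the macrophage-like and endothelial-like values most, with 58782 wild-type and 77531 deletion UMIs.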

Other observations

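The tests of the mix of Myh4-leading and Myh1-leading nuclei, of mitochondrial RNA and of free RNA were chosen after the results they bear on had been seen; both gene span tests were set before their values were seen, and the reading of the Dmd value was brought back afterwards to the bound set beforehand. Some values belong to no comparison above. Immediate-early genes had a median log2 ratio of -0.13 over all nuclei, at percentile 23.6, in which Fos, at 0.448 and 3.49 CPM, had a ratio of 7.79 (3.80 to 17.6), while Atf3 (0.535), Jun (0.611) and Dusp1 (0.941) were lower in the deletion library. Haemoglobin genes, from blood, were all lower, with a median of -1.25 over 3 genes at percentile 1.33; Hba-a2 had a ratio of 0.390 and Hbb-bs of 0.632. Both libraries held Y-linked RNA, with 6806 and 4624 UMIs of Uty and 1316 and 650 of Ddx3y, so both hold nuclei of male mice, and the 4 measured genes of that list had a median of 0.19 with Uty highest at 1.43 and Eif2s3y lowest at 0.871.

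Mitochondrially encoded genes varied by class, with medians of 0.63 in tenocyte-like, 0.46 in myoblast-like, 0.28 in FAP-like, 0.11 in satellite cell-like, 0.10 in endothelial-like and -0.38 in macrophage-like nuclei. The endothelial value has no firm direction, as TMM scaling lowers it by more than its size. Interferon genes had medians of 0.34 in FAP-like, 0.16 in macrophage-like and -0.49 in endothelial-like nuclei, each from 5 or 6 genes. Ttn reached 35.6% of its myonuclear level in wild-type Schwann cell-like nuclei and 3.97% in those of the deletion library, and 13.4% and 39.4% in smooth muscle or pericyte-like nuclei.

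The first pattern weighed was the lower level of nuclear-encoded respiration genes in myonucleus-like nuclei of the deletion library. For another mix of Myh4-leading and Myh1-leading nuclei as the whole source, the list's median stayed below 0 in both sets of clusters, at -0.24 and -0.29. Myh2 was also still lower within both sets, with a ratio of 0.626 in the Myh4-leading clusters. The split therefore does not show that the mix of fibre types was held equal, and it cannot decide on this source. For nuclei with more mitochondrial RNA as the source, the median was -0.52 over nuclei with at most 1% mitochondrial UMIs. In those nuclei the Myh2 ratio was 0.281 and the Myh4 ratio 1.69, and the genes of the shortest spans had a median log2 ratio of -0.61. That subset thus also differed in its heavy chains and kept the trend with span, so its value cannot decide on this source. A bias with gene length may account for part of the lower level of respiration genes. Among random lists matched on expression and span, whose median was -0.19, the list was at percentile 3.63, inside the middle 95%. The genotype and any other difference between the 2 libraries stay open too, and were not tested.

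The second pattern was the higher level of Dmd in the myonucleus-like nuclei of the deletion library. Among 198 other genes with a span of at least 500 kb and at least 50 UMIs, the Dmd ratio of 1.48 was at percentile 79.8, and 40 had a higher ratio. The median ratio of those genes was 1.16, and their middle 95% went from 0.557 to 3.62. The Dmd ratio thus lay inside the middle 95%, the outcome set beforehand for a bias with gene length. That spread also holds differences particular to each gene, and the median of 1.16 is below 1.48. The test therefore cannot tell a length bias from another cause. The hypothesis that the deletion itself raises nuclear Dmd RNA was not tested on its own.

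The third pattern was the higher level of Runx1 in satellite cell-like and FAP-like nuclei of the deletion library, where myonucleus-like nuclei also held more of it. If free RNA that follows Ttn gave the Runx1 counts, the level would be 77.0 CPM in satellite cell-like and 27.8 CPM in FAP-like nuclei. The measured levels were 3290 and 271 CPM, 42.8-fold and 9.73-fold above, with lower bounds of 40.0 and 8.42. This argues against free RNA that follows Ttn as the source in both classes. Free RNA from cells other than fibres need not follow Ttn and was not examined. Doublets left after removal and differences between the libraries other than genotype stay open. A biological difference with genotype is a candidate explanation, found and tested on the same 2 libraries.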
